A study of Mus musculus with 21 samples.

How the data were processed

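The series held 21 samples in 9 groups, all from C57BL/6 mice. For 8 ATAC-seq samples (4 sorted colon stromal populations with 2 libraries each, 12 weeks, male) the peak lists of each population were used, and for 1 single-cell sample (wild type, 2% DSS, D3, 12 weeks, female) the filtered and raw count matrices. The 12 bulk colon RNA samples (wild type and Map3k2-/-, water or 2% DSS at D1, 16 weeks) were not analysed here, so no comparison between genotypes was made.

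Cells for ATAC-seq were sorted by flow cytometry as gp38-positive cells negative for CD45, Epcam and CD31 with further antibodies for each subset, per the labels' protocols; the antibodies that define MRISC are not given in the sources used here. The 8 deposited peak lists give 1 score per peak, and the authors used bcl2fastq and bedtools with genome build mm10, per the submitters' processing notes. The peak caller, the meaning of the score and how the 2 libraries of a population were combined are not given in the sources used here. Scores were only used to rank peaks within a list, since their minimum differed between lists (0.0334 in MRISC, 0.0373 in CD34 SP, 0.0324 in CD138 and 0.0467 in Myofibroblast). The deposited single-cell matrices hold whole-number UMI counts per gene and barcode, which the authors made with bcl2fastq, Cell Ranger and Seurat on build mm10, per the submitters' processing notes, and the file header gives software version 3.0.0. The library was made with 10x Genomics 3' version 2 chemistry, per the labels' protocols.

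Peaks on chromosomes 1 to 19, X and Y were kept (21 chromosomes). Overlaps were computed with an own interval search, which was compared with bedtools 2.31.1 on simulated peaks only. Genes came from GENCODE vM21 on GRCm38 (the assembly of mm10), 21938 of them protein-coding, and positions are given counted from 1. A promoter was within 1 kb of a protein-coding transcription start (alternative 2 kb). The window of a gene was its body with 10 kb on both sides (alternative 50 kb, or each peak given to the gene with the nearest start). The number of specific peaks in the windows of a fixed gene list was set against 10000 random lists of protein-coding genes matched on window length in 20 bins, with a two-sided permutation p and Benjamini-Hochberg adjustment over lists and populations. The 13 lists held R-spondins, BMP antagonists, BMP ligands, canonical and noncanonical Wnt ligands, Wnt antagonists, EGF family ligands, the MAP3K2-ERK5-KLF2 route, reactive oxygen genes, immediate early genes, inflammation-associated fibroblast genes, matrix genes and sort markers. The BMP ligand list held Bmp1 to Bmp7, of which Bmp1 encodes a protease and not a ligand. Transcription factor words (21 consensus words, both strands) were searched in the central 200 bp of each specific peak (alternatives 400 bp, the whole peak, peaks outside promoters, and Mantel-Haenszel odds ratios over 10 GC bins), and compared with the specific peaks of the other 3 populations by two-sided Fisher's exact tests. Words are short and related factors share them, so a word names a family, not a factor. Odds ratios carry 95% intervals.

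In the single-cell library, the filtered matrix held 11484 barcodes and 31053 genes, and 11376 barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept (5th to 95th percentile of depth 2704 to 11585.75 UMIs). Of the 108 left out, 84 fell under the gene minimum and 82 over the mitochondrial maximum. Scrublet in scanpy 1.11.5, given an expected rate of 9.2%, marked 0 barcodes as doublets and so did not work on this library; none were removed, and doublets remain in the groups. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 0.5) gave 15 clusters. A cluster took the name of a cell type, as in mesothelium-like, when at least 3 fixed markers were 2-fold above all other cells with at least 20 CPM and no other type had more markers than it among the 10 leading genes. It also stayed without a name when another type passed 3 markers and had at least 1 among those 10 genes, unless both were fibroblast types. Clusters with fewer than 50 cells, or named by or rich in markers of cells that are not stroma, were not counted as stromal. The remaining stromal clusters were joined by whether pooled Cd34, Cd81 and Sdc1 stood above the mean of all kept cells. Levels are pooled CPM with exact Poisson intervals and shares have exact (Clopper-Pearson) binomial intervals, both at 95% and for counting error only. A count of 0 was read as an upper limit of 3 counts over the group. Cells are not replicates, so no p-value was made from them. Shares of cells with a UMI were also computed after thinning to 3000 UMIs, which left out 736 cells below that depth. Empty droplets were the 546978 raw barcodes with 1 to 100 UMIs, and free RNA was estimated at 11.6% of the stromal UMIs from immune and epithelial genes. For a gene list, the median log2 ratio of a group against the other stromal cells (1 CPM added, genes with at least 10 UMIs) was placed among 10000 random lists matched on mean expression. Genes of both assays were joined by Ensembl identifier, and random lists for that comparison were matched on expression (10 bins) and window length (5 bins).

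Genes were named by a fixed rule: R-spondins, sort markers and the MAP3K2-ERK5-KLF2 route in full, the other lists by their most abundant members or those with most specific peaks, the 10 genes with the largest excess of specific peaks per population, the 10 leading genes of each named class, and the leading genes between the 2 largest named fibroblast classes. Single members given for contrast beside these, such as Cxcl1, Saa3, Fst, Sfrp4 and the leading genes between Cd81-high and Cd81-low cells, were chosen after their values were seen. Single values of some genes that the rule names are not reported here.

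The tests, filters, windows, gene lists, markers, words, naming rule for genes and most alternatives were chosen before the data were examined. The rule that names clusters, the groups by sort genes, the marker-list tests on peaks, the share in place of the number of peaks, lists of equal number for specific peaks (20000), the peaks above the median score for words, the ranking by excess, the Scrublet score limit of 0.3 and the gate without mesothelium-like cells were chosen after.

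The interval search, the gene list test by number, the word search and the list percentile were tested on simulated data. The share of peaks, the Mantel-Haenszel odds ratios, the ratio intervals and the percentile matched on expression and length were not. The interval search differed from bedtools by 0 over 20000 simulated peaks. The gene list test on CD34 SP specific peaks (21938 genes) found 90.0% of 10 lists of 20 genes at 2-fold and 100% at 3-fold, and gave p under 0.05 in 8.0% of 200 unchanged lists, somewhat more than 5%, so unadjusted p-values near 0.05 are weak. In the lists with a planted change, a small constant was added to each gene's count before it was multiplied. The planted change thus exceeded 2-fold and 3-fold, and detection at exactly these folds may be lower. The word search over 20000 random sequences found 100% of planted words and gave an odds ratio with a lower bound of 2.67 for words planted in 5% of sequences, and 1.15 (0.96 to 1.39) for a word not planted. The list percentile (15314 genes) found 100% of 20 lists at 1.5-fold and at 2-fold, and put 4.5% of 200 unchanged lists outside percentiles 2.5 to 97.5. In that simulation unchanged genes differed by counting noise only. Genes of the real groups also differ beyond counting noise, so these rates cannot be carried over to them.

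As checks of the labels, the total ATAC-seq lists of these male mice held 16, 18, 15 and 20 peaks on chromosome Y in MRISC, CD34 SP, CD138 and Myofibroblast, and the female single-cell library held 78701 UMIs of Xist and 1 of 4 Y-linked genes. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9.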

Results

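Open chromatin was mapped by ATAC-seq in 4 sorted stromal populations of the mouse colon, and the transcripts of single colon stromal cells were counted in 1 droplet library. The sorted populations were MRISC (Map3k2-regulated intestinal stromal cells), CD34 SP (CD34 single positive cells), CD138 (CD34-negative cells positive for CD138, the product of Sdc1) and Myofibroblast. All were sorted as gp38-positive cells negative for CD45, Epcam and CD31 from male C57BL/6 mice of 12 weeks, with 2 libraries each. Each population came with 1 list of all its peaks and 1 list of its specific peaks, so the spread between libraries could not be measured and the read depth is unknown. The single-cell library held gp38+CD90+ cells of a wild-type female mouse of 12 weeks on 2% dextran sulfate sodium (DSS), a detergent that injures the colon epithelium, taken at D3. It held 72920197 UMIs in 11376 kept cells, with a median of 6052 UMIs and 2288 genes per cell. The 12 bulk colon RNA libraries of wild-type and Map3k2-/- mice were not analysed here.

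The first comparison asked how much open chromatin the 4 stromal populations had in common and how much was found in 1 of them only. MRISC and CD34 SP shared the most open chromatin of the 6 pairs, and Myofibroblast shared the least with each of the others. Most peaks that were found in a single population were short and had low scores, so the size of the specific lists followed the weak end of each list. As a share of the total list, the specific part was smallest in CD34 SP and largest in Myofibroblast, while by number and covered bases CD138 had the most.

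The deposited total lists held 177133 peaks for MRISC, 143464 for CD34 SP, 216955 for CD138 and 179435 for Myofibroblast. The specific lists held 82527, 49634, 126610 and 112865 peaks in the same order. On chromosomes 1 to 19, X and Y, every specific peak was identical to a peak of its own total list, and 0 of them overlapped a peak of another population by 1 bp or more. The specific share of the total peaks was 46.6% in MRISC, 34.6% in CD34 SP, 58.4% in CD138 and 62.9% in Myofibroblast. Total peaks of MRISC covered 66.3 Mb and those of CD34 SP 67.6 Mb, against 53.3 Mb for CD138 and 42.4 Mb for Myofibroblast. The specific peaks covered 13.3, 7.74, 18.3 and 17.9 Mb. Median widths of specific peaks lay between 131 and 149 bp, while peaks shared with another population had medians of 415 bp in MRISC, 472 bp in CD34 SP, 311 bp in CD138 and 275 bp in Myofibroblast.

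Specific peaks lay low in the score order of every population. In MRISC, 82.4% of the peaks in the lowest quintile of scores were specific, against 1.3% in the highest quintile. In CD34 SP the specific share ran from 78.3% in the lowest quintile to 0.0% in the highest. CD138 went from 85.8% to 5.9% and Myofibroblast from 82.9% to 14.9%. With all 4 lists limited to the peaks above their median score, and specificity called again among these, 26.5% of MRISC, 11.9% of CD34 SP, 42.3% of CD138 and 50.7% of Myofibroblast peaks were specific. With all 4 lists shortened to the best-scored 143411 peaks and called again, the shares were 39.6% for MRISC, 37.3% for CD34 SP, 46.1% for CD138 and 59.3% for Myofibroblast, which brought MRISC and CD34 SP close together.

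**Figure D1:**
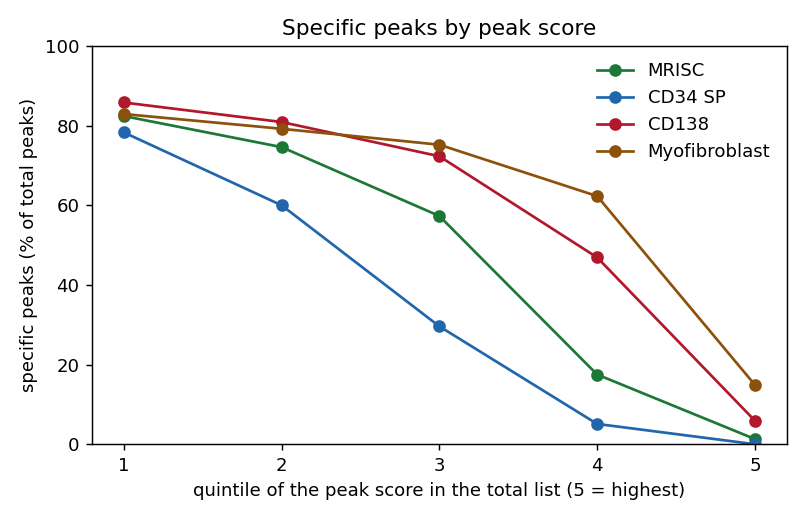
Share of total ATAC-seq peaks that were specific to the population (y axis, percent) in each quintile of the peak score from lowest to highest (x axis), 1 line per sorted population. The share fell with the score in all 4 populations, from 78.3% to 85.8% in the lowest quintile down to 0.0% to 14.9% in the highest.

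Between MRISC and CD34 SP, 46.6% of MRISC peaks and 55.0% of CD34 SP peaks overlapped, and the covered bases had a Jaccard index of 48.6%. CD34 SP and CD138 followed with a mean overlap of 40.7% and a Jaccard index of 31.8%. MRISC and CD138 had 34.6% and 29.0%. The 3 pairs with Myofibroblast were lower, at 31.3% with CD34 SP, 27.8% with MRISC and 25% with CD138. MRISC and CD34 SP stayed the closest pair when an overlap had to cover 50% of both peaks (35.7%, against 12.5% to 21.4% in the other 5 pairs) and with lists of equal number (54.0%, against 30% to 45.2%).

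The second comparison placed the specific peaks in the genome, to see whether any population used promoters more. Specific peaks were mostly distal in all populations, and least so in CD34 SP. Promoters within 1 kb of a protein-coding start held 5.09% of CD34 SP specific peaks, against 3.91% in MRISC, 2.76% in CD138 and 2.64% in Myofibroblast. Among total peaks the promoter share was 13.3%, 11.7%, 10.2% and 11.5%. The odds of a promoter position, set against the specific peaks of the other 3 populations, were 1.73 (95% interval 1.65 to 1.81, two-sided Fisher's exact p = 6.53e-114) in CD34 SP and 1.27 (1.22 to 1.32, p = 8.70e-29) in MRISC. They were 0.77 (0.74 to 0.80, exact p = 7.17e-40) in CD138 and 0.73 (0.70 to 0.76, p = 1.03e-50) in Myofibroblast. Introns held 51.1% of CD34 SP and 48.2% of MRISC specific peaks, while 50.4% of CD138 and 49.8% of Myofibroblast specific peaks were intergenic. The median distance to the nearest start was 21222 bp in CD34 SP, 29472 bp in MRISC, 40674 bp in Myofibroblast and 45141 bp in CD138. These tests compare pooled lists, in which peaks are not biological replicates.

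The third comparison asked whether genes of the stem cell niche and of the stromal state carried more population-specific open chromatin than other genes of their length. Genes for matrix proteins had more specific peaks of CD34 SP and MRISC than random genes, and immediate early genes more of CD34 SP. R-spondin genes, which encode the secreted amplifiers of Wnt signalling, had no excess in MRISC. None of these list differences passed correction over all lists and populations with the window of 10 kb around the gene.

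Of 52 permutation tests (13 lists in 4 populations, two-sided, 10000 random gene lists, Benjamini-Hochberg), 0 passed an adjusted p of 0.05 and 8 had an unadjusted p under 0.05, all with more peaks than random lists. With windows of 50 kb 7 tests passed, with peaks assigned to the nearest start 5, with the specific peaks above the median score 0, and with 20000 specific peaks per population 0. The matrix genes had 182 specific peaks of CD34 SP against 53.0 in random lists (permutation p = 0.003, adjusted 0.107) and 162 of MRISC against 78.6 (p = 0.0056, adjusted 0.107). Col5a1, which encodes a collagen that starts fibril assembly, had 47 specific peaks of MRISC and 40 of CD34 SP against 10 and 9 of CD138 and Myofibroblast. Fibronectin (Fn1) had 21 specific peaks of CD34 SP, Col15a1 had 18 and Postn (periostin) 16, while Col14a1 had 20 of MRISC. With 50 kb the specific peaks of MRISC at immediate early genes passed by number (110 against 63.8, adjusted permutation p = 0.0416). By share they did not (28.0% against 25.5%, adjusted permutation p = 0.736). With 10 kb, immediate early genes had 40 specific peaks of CD34 SP against 15 (permutation p = 0.0062, adjusted 0.107). The 40 were led by the AP-1 subunit genes Fosl2 with 10 and Fosl1 with 7. When each list was measured instead by the share of its specific peaks that came from a population, 4 tests passed, none of them of MRISC. CD34 SP then held 36.0% of those at matrix genes against 16.2% in random lists (adjusted permutation p = 0.0052) and 44.0% of those at immediate early genes against 18.8% (adjusted p = 0.0338). The other 2 shares that passed, those of CD138 (15.6% against 31.2%, adjusted permutation p = 0.0052) and Myofibroblast (16.2% against 28.6%, adjusted p = 0.0104) at matrix genes, are parts of the same total and fall when CD34 SP and MRISC rise. By number, CD138 had 79 there against 101.6 (permutation p = 0.242) and Myofibroblast 82 against 93.0 (p = 0.615), so neither was shown to be depleted.

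BMP ligand genes had 48 specific peaks of CD34 SP against 19.5 in random lists (permutation p = 0.0196, adjusted 0.255, and 0.0166 by the nearest start), of which Bmp5 carried 15 and Bmp6 13, and 55 of CD138 against 35.7 (p = 0.046, adjusted 0.294, and 0.0416 with 50 kb), of which Bmp5 carried 19 and Bmp6 17. By share, BMP ligand genes did not pass in CD34 SP by the nearest start (22.0% against 14.1%, adjusted permutation p = 0.761). In CD138 with 50 kb they did not either (36.0% against 30.4%, adjusted permutation p = 0.53). BMP antagonist genes had 40, 22, 44 and 37 specific peaks in MRISC, CD34 SP, CD138 and Myofibroblast against 38.9, 25.9, 53.0 and 47.5. Among them Grem1, the gene of the BMP antagonist gremlin 1, had 9 in MRISC, 6 in CD34 SP, 1 in CD138 and 3 in Myofibroblast. Fstl1 had 11 in MRISC and Bmper 23 in CD138. Canonical Wnt ligand genes had 34 of Myofibroblast against 20 (permutation p = 0.0304, adjusted 0.294, and 0.0364 with 50 kb), with 10 at Wnt3. By share they did not pass with 50 kb (35.8% against 28.5%, adjusted permutation p = 0.268). The windows of Wnt6 and Wnt10a overlap, and with 50 kb those of Wnt3 and Wnt9b do too, so a peak can count for both genes. Noncanonical Wnt ligand genes had 24 of MRISC against 14.0 (permutation p = 0.16), of which Wnt5b carried 16. By the nearest start they had 89 against 16.7 (adjusted permutation p = 0.0104), but not by share (31.1% against 22.9%, adjusted permutation p = 0.812). Wnt antagonist genes had 33, 24, 33 and 26 against 24.1, 17.4, 28.0 and 26.7, with 8 of MRISC and 8 of CD34 SP at Sfrp1. EGF family genes had 32, 37, 85 and 75 against 36.4, 23.8, 49.8 and 44.7. The neuregulin gene Nrg1 carried 56 of those in CD138 and 51 of those in Myofibroblast, while Ereg (epiregulin) carried 15 of those in CD34 SP. Genes of inflammation-associated fibroblasts had 39 of CD34 SP against 21.8 (permutation p = 0.0426, adjusted 0.294, but 0.0104 with 50 kb and 0.013 by the nearest start), with 8 at Ptgs2 (cyclooxygenase 2), and 44 of MRISC against 29.0 (p = 0.075), with 7 each at Ccl2, Ccl7 and Il33. The windows of the neighbouring genes Ccl2 and Ccl7 overlap, so a peak can count for both. Random lists were not matched on such overlap, which can raise the number for this list. Genes that make or remove reactive oxygen had 59, 46, 50 and 44 against 43.2, 31.8, 48.8 and 47.5, with 8 of MRISC at the thioredoxin reductase gene Txnrd1 and 7 at the NADPH oxidase gene Nox4.

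The R-spondin genes had 13 specific peaks in MRISC, 7 in CD34 SP, 21 in CD138 and 18 in Myofibroblast, against 17.7, 12.1, 22.5 and 20.9 in random lists (MRISC permutation p = 0.642). Rspo1 (ENSMUSG00000028871, chromosome 4, 124986430 to 125009099, mm10, plus strand) had 4 specific peaks in MRISC, 2 in CD34 SP, 2 in CD138 and 1 in Myofibroblast, among 7, 5, 4 and 3 total peaks. The MRISC peaks at Rspo1 were 124980670 to 124980809 and 124981449 to 124981590 upstream of the gene, 124991908 to 124991956 in an intron, and 125014346 to 125014474 downstream. Their scores stood at percentiles 20, 33.8, 4.1 and 30.2 of all MRISC peaks. Rspo2 had 5, 1, 8 and 7 specific peaks in MRISC, CD34 SP, CD138 and Myofibroblast, Rspo3 had 3, 3, 7 and 3, and Rspo4 had 1, 1, 4 and 7.

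The route from the kinase MAP3K2 through MEK5 and ERK5 to the transcription factor KLF2 had 55 specific peaks in MRISC, 39 in CD34 SP, 68 in CD138 and 41 in Myofibroblast, against 46.0, 29.9, 63.3 and 56.8 (MRISC permutation p = 0.498). Map3k2 itself (chromosome 18, 32163089 to 32236751) had 6, 5, 7 and 5 in that order, and its paralog Map3k3 had 9, 3, 11 and 3. The MEK5 gene Map2k5 had 12, 4, 11 and 8, and the ERK5 gene Mapk7 had 2, 0, 2 and 1. The MEF2 factors, which are ERK5 substrates, had 4, 5, 8 and 6 at Mef2a, 4, 2, 20 and 11 at Mef2c, and 9, 9, 4 and 2 at Mef2d. Klf2 (chromosome 8, 72319033 to 72321656) had 3, 1, 2 and 3 specific peaks among 12, 7, 13 and 7 total peaks. Klf4 had 3, 1, 0 and 2, and Klf6 had 3, 9, 3 and 0.

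The genes of the sort markers checked the labels in part. Cd81 (chromosome 7, 143052739 to 143067934), which encodes a tetraspanin, had 11 specific peaks in MRISC, 0 in CD34 SP, 4 in CD138 and 5 in Myofibroblast. Cd34 (chromosome 1, 194938819 to 194961279) had 6, 3, 2 and 2, and Sdc1 had 5, 2, 9 and 7. Pdpn, the gp38 gene, had 3, 15, 0 and 2, and Thy1, the CD90 gene, had 0, 5, 3 and 0. Of the genes sorted against, Ptprc (CD45) had 2, 1, 12 and 6, Epcam 0, 0, 4 and 0, and Pecam1 (CD31) 17, 6, 13 and 5. The list as a whole had 47 specific peaks of CD138 against 30.1 in random lists (permutation p = 0.0496, adjusted 0.294).

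The fixed marker genes of colon cell types were then tested in the same way, a test chosen after the lists were examined. Of 72 tests (18 marker lists in 4 populations), 1 passed an adjusted p of 0.05 and 11 had an unadjusted p under 0.05. The markers of CD34+CD81+ fibroblasts had 43 specific peaks of MRISC against 12.6 in random lists (permutation p = 2.00e-04, the smallest these permutations can give, adjusted 0.0144). Cd81 carried 11 of them, Ackr4, the gene of a chemokine-scavenging receptor, 9, the complement gene C3 9, Sfrp1 8 and Cd34 6. By share, MRISC held 45.3% of the specific peaks at these genes against 25% (adjusted permutation p = 0.425), and 0 of the 72 tests passed. Markers of myofibroblasts and smooth muscle had 51 specific peaks of Myofibroblast against 26.6 (permutation p = 0.0034) and 50 of CD138 against 28.1 (p = 0.0112), neither past correction.

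The genes with the largest excess of specific peaks over the mean of the other populations were then listed. In MRISC they included Gm20388, Slit3, Ebf1, Rbfox3, Phactr1, Rora, Col5a1, Pcsk5 and Meis2. Slit3, a secreted guidance cue, had 94 specific peaks in MRISC against 28 in CD34 SP, 44 in CD138 and 52 in Myofibroblast. Ebf1, the gene of a transcription factor of mesenchymal and B cell lineages (chromosome 11, 44617317 to 45008091), had 65 against 7, 30 and 20. The homeodomain factor gene Meis2 had 35 against 8 in CD34 SP, and the nuclear receptor gene Rora had 80 against 34. Gm20388 is a gene model of 4434.9 kb that spans many other genes, and its 395 peaks belong to that whole stretch.

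In CD34 SP the genes were Jak1, Hk2, Ext1, Arid5b, Rad51b, Zeb2, St5, Timp3, Cd44 and Fndc3b. The cytokine receptor kinase gene Jak1 had 42 specific peaks in CD34 SP against 22 in MRISC, 7 in CD138 and 6 in Myofibroblast. Hk2, the gene of a glycolytic hexokinase, had 33 against 10, 1 and 1, and Timp3, the gene of a matrix-bound protease inhibitor, had 21 against 1, 1 and 2. Cd44, the gene of the hyaluronan receptor, had 30 against 11, 13 and 7. In CD138 the genes were Macrod2, Dlg2, Lsamp, Cntnap2, Csmd1, Fhit, Ptprd, Nrxn3, Pcdh15 and Pde4d, and in Myofibroblast Rbfox1, Dpp6, Ntm, Ctnnd2, Kirrel3, Csmd1, St6galnac3, Grin2a, Ctnna2 and Nav2. Macrod2 had 123 specific peaks in CD138 and 82 in Myofibroblast, and Rbfox1 had 99 and 97. Csmd1, in both lists, had 106 and 84, and Nav2, in the Myofibroblast list, had 90 and 77. These lists followed gene length, with a median of 1807.8 kb for the CD138 genes and 883.5 kb for the Myofibroblast genes, against 413.6 kb for MRISC, 156.8 kb for CD34 SP and 17.4 kb for all protein-coding genes.

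The fourth comparison searched the specific peaks for short words that transcription factors recognise, to see which factors could bind each population's own open chromatin. CD34 SP peaks were rich in AP-1, CTCF, E-box and TEAD words. MRISC peaks had more glucocorticoid receptor words than the others and, with CD34 SP, more KLF/SP, AP-1 and NF-kB words. The NF-kB call in CD34 SP was lost with equal numbers. CD138 peaks had more ETS, RUNX, IRF and FOX words, and Myofibroblast peaks more MEF2 and SRF words.

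Of 84 two-sided Fisher's exact tests (21 words in 4 populations, Benjamini-Hochberg), 61 passed an adjusted p of 0.05, of which 31 were more frequent and 30 less frequent than in the specific peaks of the other 3 populations. CD34 SP had 12 of the more frequent words, CD138 8, MRISC 7 and Myofibroblast 4. The AP-1 word, bound by FOS and JUN dimers, was in 9.31% of CD34 SP specific peaks, 6.05% of MRISC, 4.50% of CD138 and 4.14% of Myofibroblast. Its odds ratio was 2.05 (1.98 to 2.12) in CD34 SP, 1.18 (1.14 to 1.22) in MRISC, 0.76 (0.74 to 0.79) in CD138 and 0.69 (0.66 to 0.71) in Myofibroblast. The word of the insulator protein CTCF had 2.53 (2.22 to 2.89) in CD34 SP and 0.27 (0.22 to 0.33) in Myofibroblast. The E-box and TEAD words had 1.38 (1.35 to 1.42) and 1.34 (1.28 to 1.40) in CD34 SP. The KLF/SP word, which KLF2 and its relatives bind, had 1.29 (1.24 to 1.33) in CD34 SP and 1.18 (1.14 to 1.21) in MRISC, against 0.92 (0.89 to 0.94) in CD138 (not past correction with equal numbers, 0.99, or within GC bins, 0.99) and 0.82 (0.80 to 0.84) in Myofibroblast. Glucocorticoid receptor words were in 307 specific peaks of MRISC (0.37%, against 0.22% in the others), an odds ratio of 1.71 (1.49 to 1.96), which rose to 2.68 (2.11 to 3.40) with the 20000 best-scored specific peaks of each population, and had 0.70 (0.60 to 0.82) in Myofibroblast. NF-kB words had 1.16 (1.11 to 1.23) in MRISC and 1.22 (1.15 to 1.30) in CD34 SP, the second of which did not pass correction with equal numbers (1.08, 0.98 to 1.20).

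In CD138 the ETS word had an odds ratio of 1.36 (1.32 to 1.41, and 2.18, 2.03 to 2.33, with equal numbers), the RUNX word 1.32 (1.26 to 1.37), the IRF word 1.24 (1.19 to 1.30) and the FOX word 1.21 (1.16 to 1.26). The MEF2 word, of factors that ERK5 activates, was most frequent in Myofibroblast at 1.24 (1.19 to 1.29) and less frequent in MRISC at 0.78 (0.74 to 0.83) and CD34 SP at 0.84 (0.78 to 0.89). The call in CD34 SP was lost in the whole peak (0.93), within GC bins (0.95) and with equal numbers (0.94, 0.84 to 1.05). The SRF word of contractile genes had 1.13 (1.06 to 1.21) in Myofibroblast. The TCF/LEF word of canonical Wnt targets did not differ in any of the 4 populations (odds ratios 0.97 to 1.04, adjusted p of 0.429 or more). Weak calls in MRISC for the E-box (1.03) and NRF2 (1.05) words and in CD138 for the MEF2 (1.06), GATA (1.07) and SOX (1.06) words changed direction under other settings. Of the 61 calls, 59 were kept with 400 bp, 53 in the whole peak, 59 outside promoters, 54 within GC bins, 58 above the median score and 46 with equal numbers.

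**Figure D2:**
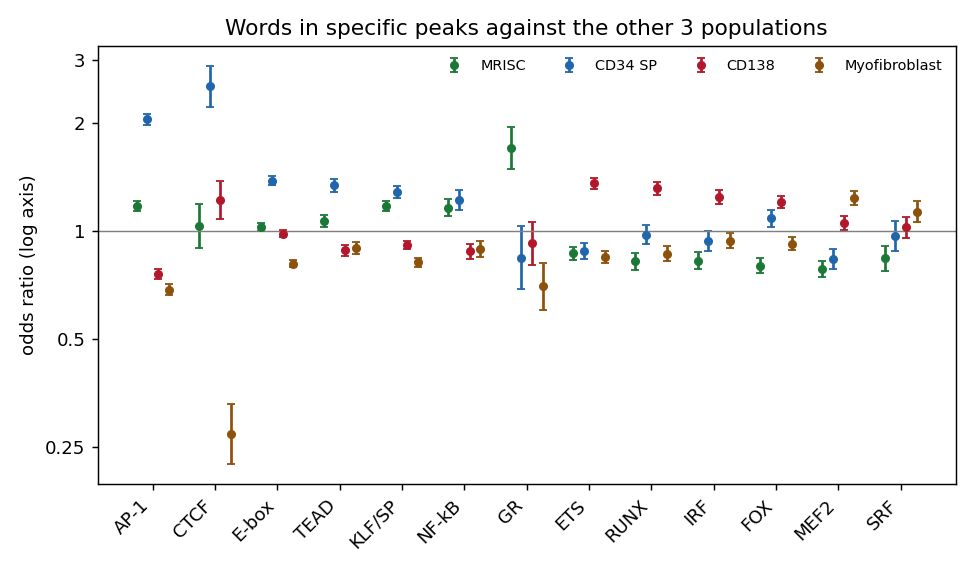
Odds ratios (log axis) of 13 transcription factor words in the specific ATAC-seq peaks of each sorted population against those of the other 3, with 95% intervals as bars. The AP-1 and CTCF words stood highest in CD34 SP, at 2.05 and 2.53, and the glucocorticoid receptor word in MRISC, at 1.71.

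The fifth comparison sorted the cells of the single-cell library into types and into groups taken as transcript counterparts of the sorted populations. That these groups match the sorted populations was assumed and not tested. The library was made of stromal cells, in 15 clusters of which 11 were stromal with 50 cells or more. Adventitial-like fibroblasts formed 1 of the 2 clusters with high Cd34 and high Cd81. Mesothelium-like cells were rare, and so were crypt-top-like cells except with 4000 variable genes.

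Clusters with Cd34 and Cd81 above the mean of all kept cells held 1358 cells, 11.9% of the total (exact binomial 95% interval 11.4% to 12.6%), and are called Cd81-high. Clusters with high Cd34 and low Cd81 held 4287 cells (37.7%, 36.8% to 38.6%), called Cd81-low, and clusters with low Cd34 and high Sdc1 held 2047 (18%, 17.3% to 18.7%), called Sdc1-high. Pooled Cd81 stood at 782.6 CPM (UMIs of a gene scaled to a common total) in Cd81-high, 80.6 in Cd81-low and 40.8 in Sdc1-high cells. Pooled Cd34 stood at 643.4, 688.0 and 186.0 CPM and Sdc1 at 24.1, 80.3 and 269.6 CPM, which follows from how the groups were made. Pdpn had 244.6, 346.4 and 262.9 CPM and Thy1 151.5, 202.6 and 130.9 CPM in that order. Epcam had 0.9, 1.0 and 1.4 CPM, Pecam1 0.9, 1.5 and 1.2 CPM, and Ptprc had 1 UMI in Cd81-low and none in the other 2 groups, which allows up to 0.37 CPM in Cd81-high and 0.21 in Sdc1-high cells. These intervals cover counting error only, since 1 library has no replicates.

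Fixed markers named 6 of the 15 clusters. Myofibroblast or smooth muscle-like cells (1078, 9.48%) were led by Myh11, Actg2, Cnn1, Hhip, Lmod1, Actc1, Cdh6, Tinagl1, Asb2 and Dtna. Adventitial-like cells (876, 7.70%), in 1 of the 2 Cd81-high clusters, were led by Npy1r, Ackr4, Pcolce2, Ebf1, Adamtsl3, Cilp, Prss23, Has1, Fap and Pi16. The other Cd81-high cluster (482 cells) was led by Ptx3, Ctla2a, Ptn, Inmt, Gdf10, Ebf2, Sfrp4, Myoc, Fst and Wt1. It passed 4 adventitial markers, but its leading genes held the mesothelial marker Wt1 and no adventitial one, so it stayed without a name. Mesothelium-like cells (88, 0.77%, interval 0.62% to 0.95%) were led by Slpi, Msln, Upk3b, Gpm6a, Lrrn4, Upk1b, Lgals7, Prr15, Chst4 and Cxadr. Pdgfra-high crypt-top-like cells (79, 0.69%, interval 0.55% to 0.86%) were led by Wif1, Sox6, Ednrb, Bmp3, Tspan13, Procr, Fgf9, Cybrd1, Mt3 and Egflam. With 4000 variable genes the crypt-top-like class held 650 cells (5.71%) and its Rspo1 was 41.7 CPM in place of 3.8, so its extent depended on the clustering. A further 37 dividing-like cells, led by the immune genes Gzma and Gzmb, and 33 epithelium-like cells were not counted as stroma. The 9 clusters without a name, kept out by a naming rule set after the data were seen, held 9185 cells, 80.7% of the total (80.0% to 81.5%). One of these, with 335 cells, was led by the plasma cell genes Jchain, Igkc, Igha and Mzb1 and the macrophage gene C1qb, and was not counted as stroma. Its cells also held stromal RNA, with Cd34 at 495.7 CPM and a Cd34 UMI in 83.9% of them.

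The sixth comparison asked which stromal cells held the transcripts of niche signals that keep intestinal stem cells dividing. Rspo1 and Rspo3 were both abundant in Cd81-high cells and scarce in Cd81-low cells. Pooled Rspo1 was at the same level in Sdc1-high cells, though their 2 clusters differed, and far higher in the rare mesothelium-like cells. Grem1 was highest in Cd81-high cells, and mainly in 1 of their 2 clusters. BMP ligand transcripts were low in Cd81-high cells.

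Pooled Rspo1 stood at 54.1 CPM (exact Poisson 95% interval 49.2 to 59.3) in Cd81-high, 2.1 (1.6 to 2.8) in Cd81-low and 53.3 (49.6 to 57.2) in Sdc1-high cells, against 24.7 CPM in empty droplets. The ratio of Cd81-high to Cd81-low was 25.3 (19 to 34.2), and it was 8.95 with the looser cell filter and 5.67 with 20 principal components. With the empty droplet profile subtracted, Cd81-high cells had 57.9 CPM and Cd81-low cells 0.0, so no ratio exists there. The pooled averages of Cd81-high and Sdc1-high cells did not differ at this depth (ratio 1.01, 0.90 to 1.14), and which of them was higher changed with the clustering. Of the 2 Sdc1-high clusters, the one led by Mmp10 had 29.5 CPM (25.9 to 33.4) and the one led by Ces1f 86.2 (79.1 to 93.9). Mesothelium-like cells had 526.0 CPM (477.1 to 578.5) and 20.7% of all Rspo1 UMIs in 0.77% of the cells. A UMI of Rspo1 was found in 22.8% of Cd81-high cells (20.6% to 25.2%, 13.2% after thinning to 3000 UMIs, median depth 5593 UMIs). It was found in 1.24% of Cd81-low cells (0.40% thinned, median 5810), 23.8% of Sdc1-high cells (12.4% thinned, median 6758) and 77.3% of mesothelium-like cells (76.7% thinned, median 9700.5). Cells not counted as stroma had a UMI in 5.42% (3.09% thinned, median 6206), but most of them carried stromal RNA, so they give no level for cells without Rspo1.

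Rspo3 stood at 86.3 CPM (80.1 to 92.9) in Cd81-high, 9.1 (7.9 to 10.3) in Cd81-low and 15.3 (13.4 to 17.5) in Sdc1-high cells, with 18.3 CPM in empty droplets. Its ratio of Cd81-high to Cd81-low was 9.52 (8.19 to 11.1) and to Sdc1-high 5.64 (4.85 to 6.58), and mesothelium-like cells had 5.0 CPM. A cluster of 50 cells led by Igfbp2 and Rgs5, counted with the remaining stromal cells, had 180.2 CPM of Rspo3 (132.4 to 239.6) and 314.3 of Grem1 (250.0 to 390.2). Its Rspo3 exceeded that of both Cd81-high clusters (79.2 and 96.3 CPM). This cluster passed the myofibroblast or smooth muscle markers Acta2, Tagln, Myh11, Actg2, Des, Cnn1 and Npnt. None of these was among its leading genes, which held the pericyte marker Rgs5, so it stayed without a name. Of its cells, 12.0% had a Scrublet score above 0.3. Rspo2 had 2.1, 0.1 and 1.8 CPM in the 3 groups, and Rspo4 had no UMI, which allows up to 0.37, 0.12 and 0.21 CPM. Grem1 stood at 396.4 CPM (382.9 to 410.3) in Cd81-high, 161.3 in Cd81-low, 246.9 in Sdc1-high and 53.4 in myofibroblast-like cells (27.0 without Scrublet scores above 0.3), with 164.7 CPM in empty droplets. Grem1 was 2.46-fold (2.35 to 2.57) higher in Cd81-high than in Cd81-low cells. Of the 2 Cd81-high clusters, the one led by Npy1r had 608.9 CPM of Grem1 and 37.1 of Rspo1, and the one led by Ptx3 had 101.3 of Grem1 and 77.7 of Rspo1. As a list, R-spondins had a median log2 ratio of 1.05 in Cd81-high cells against the other stromal cells (percentile 99.7 of 10000 random lists of matched expression), −1.67 in Cd81-low (0.02) and 0.85 in Sdc1-high (99.7, and 89.7 among genes with at least 100 UMIs). With no UMI of Rspo4 in these groups, the percentiles largely restate the levels of Rspo1, Rspo2 and Rspo3.

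**Figure D3:**
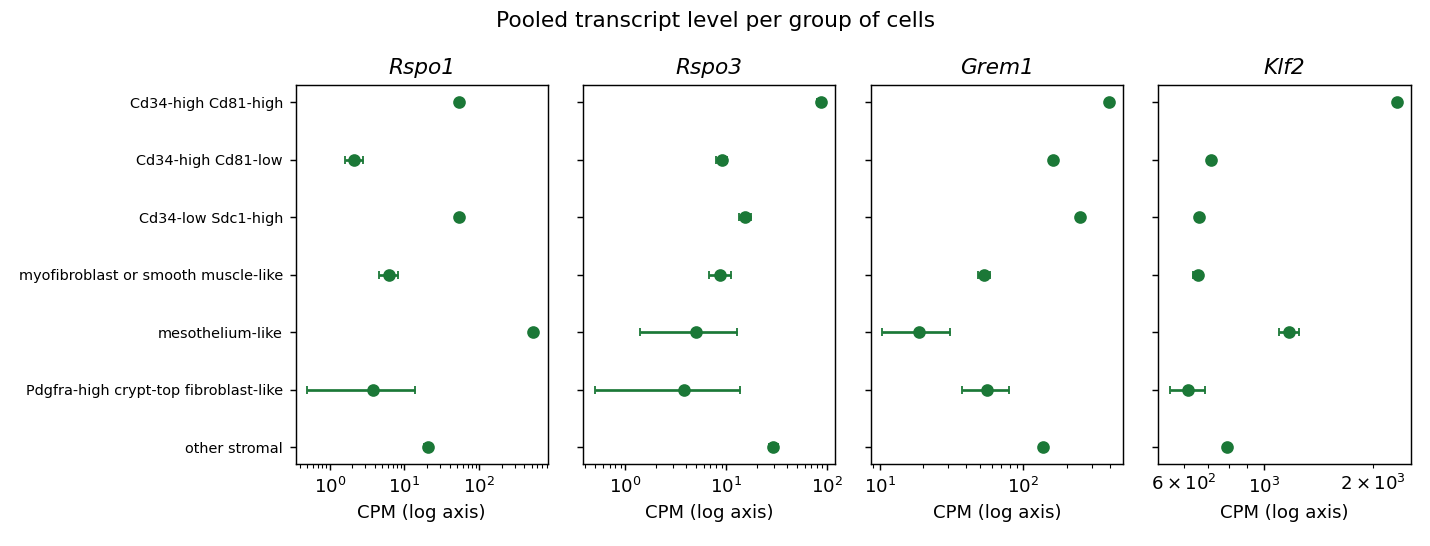
Pooled CPM (log axis) of Rspo1, Rspo3, Grem1 and Klf2 in 7 stromal groups of the single-cell library, with exact Poisson 95% intervals as bars (counting error only). Rspo1 stood at 526.0 CPM in mesothelium-like cells, and among these 7 groups Rspo3, Grem1 and Klf2 were highest in Cd81-high cells.

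BMP antagonists as a list were higher in Cd81-high cells (median log2 ratio 1.30, percentile 100 of random lists, 5 of 9 genes at least 2-fold higher and 1 lower). Fstl1 had 844.2 CPM there, 600.5 in Cd81-low and 549.5 in Sdc1-high cells, and the follistatin gene Fst had 67.3, 0.5 and 10.9. The Cd81-high cluster led by Ptx3 carried most of that Fst, with 148.4 CPM against 3.8 in all other kept cells. BMP ligands were lower in Cd81-high cells (−0.97, percentile 0.11, 0 of 7 genes higher and 3 lower) and higher in crypt-top-like cells (2.36, percentile 100). The 7 genes include Bmp1, the gene of a protease. Bmp4 had 313.0 CPM (301.0 to 325.3) in Cd81-high, 1116.1 in Cd81-low and 888.9 in Sdc1-high cells. In crypt-top-like cells Bmp2 had 661.7 and Bmp5 504.9 CPM. Canonical Wnt ligands had percentile 0.38 in Cd81-high and 95.2 in Cd81-low cells, where Wnt2 had 8.8 and 28.2 and Wnt2b 8.2 and 20.1 CPM. Noncanonical Wnt ligands had percentiles 3.53, 82.3 and 93.9 in Cd81-high, Cd81-low and Sdc1-high cells. Wnt4 had 34.1, 242.2 and 299.9 CPM in those groups, and Wnt5a had 379.6 CPM in mesothelium-like and 208.4 in crypt-top-like cells. Wnt antagonists had low medians in all 7 groups (percentiles 0.0 to 0.12), but among genes with at least 100 UMIs they stood at 99.2 in the remaining stromal cells and 12.2 in Cd81-low cells. Sfrp4 had 307.5 CPM in Cd81-high and 4.3 in Cd81-low cells, and Sfrp1 1349.6 in the remaining stromal cells. EGF family ligands were high in Sdc1-high cells (percentile 99.96), with Ereg at 988.7 CPM against 96.6 in Cd81-high cells, and Nrg1 at 581.7 against 23.0.

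The kinase route named in the study's title was then followed at the transcript level. Map3k2 itself showed no detectable difference between these groups and stood at the level of empty droplets, while its distal target Klf2 was highest in Cd81-high cells. Map3k2 stood at 36.4 CPM (32.4 to 40.8) in Cd81-high, 36.2 (33.9 to 38.6) in Cd81-low and 39.4 (36.2 to 42.7) in Sdc1-high cells, with 36.3 CPM in empty droplets. With the empty droplet profile subtracted it was 36.4, 36.2 and 39.8 CPM. An equal level in cells and droplets does not by itself show that these UMIs are free RNA. The Cd81-high to Cd81-low ratio of Map3k2 was 1.01 (0.88 to 1.15). Map3k3 had 7.9, 7.7 and 7.6 CPM, Map2k5 20.5, 23.7 and 31.0, and Mapk7 18.5, 21.7 and 22.6. Mef2a had 59.6, 55.6 and 44.8 CPM, Mef2d 24.2, 30.6 and 30.2, and Mef2c 13.4, 6.6 and 13.3 with 81.0 in myofibroblast-like cells. Klf2, which ERK5 induces through MEF2, stood at 2325.0 CPM (2292.1 to 2358.2) in Cd81-high cells, 712.7 in Cd81-low and 661.7 in Sdc1-high, with 1173.6 in mesothelium-like cells and 1124.6 in empty droplets. Its Cd81-high to Cd81-low ratio was 3.26 (3.20 to 3.33). Klf4 had 941.3, 554.5 and 371.1 CPM and Klf6 549.9, 242.4 and 274.0. As a list the route stood at percentile 93.9 in Cd81-high cells (median log2 ratio 0.01, 2 of 10 genes at least 2-fold higher), so the difference rested on the KLF genes at its end.

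Klf2 did not rise alone. Immediate early genes, which respond to stimulation and to tissue handling within minutes, were higher in Cd81-high cells (median log2 ratio 1.19, percentile 100, 7 of 12 at least 2-fold higher) and lower in Cd81-low cells (−0.93, percentile 0.0, 6 lower). Fos had 6033.8, 1911.4 and 2875.9 CPM in Cd81-high, Cd81-low and Sdc1-high cells, Junb 4440.5, 1424.5 and 2967.8, and Jun 3373.2, 1774.9 and 2632.8. Mesothelium-like (percentile 99.9) and Sdc1-high cells (99.8) also had high immediate early genes. Genes of inflammation-associated fibroblasts stood at percentile 99.6 in Cd81-high cells, with 6 of 18 higher and 6 lower, and at 100 in Sdc1-high cells, with 8 higher and 3 lower. Cd81-low cells had 12 of these 18 genes at least 2-fold lower. Cxcl12, the most abundant, had 1745.6, 2863.0 and 2464.8 CPM, and Cxcl1 had 1505.3, 113.3 and 441.7. Saa3 (serum amyloid A3) had 1278.5 CPM in Sdc1-high cells against 271.2 in Cd81-high. Matrix genes were highest in the remaining stromal cells (percentile 100) and lowest in myofibroblast-like (0.0) and mesothelium-like cells (0.0), and Dcn (decorin) had 15134.7 CPM in Cd81-high, 9477.3 in Cd81-low and 2543.1 in myofibroblast-like cells. Reactive oxygen genes stood at percentiles 74.8 in Cd81-high, 0.31 in Cd81-low and 73.6 in Sdc1-high cells, with Gpx3 at 1061.3, 933.9 and 1049.2 CPM. The sort marker list stood at percentiles 28.7, 95.1 and 13.2 in these groups, the first of which was 84.8 among genes with at least 100 UMIs.

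The seventh comparison repeated the sort on transcripts, cell by cell, after thinning each cell to 3000 UMIs. Cells with both Cd34 and Cd81 had more Rspo1, Rspo3, Grem1 and Klf2 than cells with Cd34 alone, and the same Map3k2. The highest Rspo1 was in cells with Cd81 alone, of which 6.6% were mesothelium-like. A cell without a UMI of a gene can still express it.

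Rspo1 stood at 40.9 CPM (35.2 to 47.2) in the 1500 cells with both transcripts, 9.1 (7.6 to 10.8) in the 4712 with Cd34 only, 71.0 (58.2 to 85.9) in the 502 with Cd81 only, and 61.6 (52.5 to 71.8) in the 877 with Sdc1 and neither Cd34 nor Cd81. The 2661 cells with none of the 3 had 20.8 (17.8 to 24.2). Cells with both exceeded those with Cd34 only 4.49-fold (3.57 to 5.67) in Rspo1, 3.55-fold (2.93 to 4.31) in Rspo3, 2.15-fold (2.02 to 2.30) in Grem1 and 2.13-fold (2.07 to 2.20) in Klf2. Map3k2 had a ratio of 1.04 (0.87 to 1.24). Of the cells with both, 50.9% were in the Cd81-high clusters and 2.3% were mesothelium-like. Without mesothelium-like cells, Rspo1 was 30.5 CPM in cells with both transcripts, 8.9 with Cd34 only and 37.7 with Cd81 only, and the 61.6 CPM of cells with Sdc1 was then the highest.

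The 2 named fibroblast classes, adventitial-like and crypt-top-like, differed in many of the genes that define them, which are given as identity. Chil1, the gene of a chitinase-like protein, was at least 25.5-fold higher in adventitial-like cells, against a floor of 3 counts over the 79 crypt-top-like cells. Ebf1 was 134.6-fold (37.2 to 1112.2) higher, Has1 (a hyaluronan synthase) 57.2-fold (24.5 to 176.2) and Pi16 35.7-fold (18.1 to 82.8). In crypt-top-like cells the Wnt inhibitor gene Wif1 was at least 200.8-fold higher, the endothelin receptor gene Ednrb 239.2-fold (99.9 to 748.9), Sox6 374.3-fold (100.4 to 3142.7) and Bmp7 59.6-fold (36.6 to 102.3). Between the Cd81-high and Cd81-low groups, a comparison added after the data were seen, Ebf1 was 117.8-fold (97.9 to 143.0) and the pentraxin gene Ptx3 129.9-fold (105.0 to 162.5) higher in Cd81-high. Most of the Ptx3 was in the smaller Cd81-high cluster that it led, with 991.0 CPM against 7.5 in all other kept cells. Ackr4 was 160.2-fold (86.4 to 336.1) higher in Cd81-high than in Cd81-low cells. In Cd81-low cells the chemokine gene Cxcl13 was 7.9-fold (7.2 to 8.7), Wnt4 7.1-fold (6.3 to 8.0) and Igfbp3 6.3-fold (6.0 to 6.6) higher. Most of the Cxcl13 was in the Cd81-low cluster that it led, with 884.5 CPM against 441.3 in the whole group. Ebf1 was thus both among the 10 leading MRISC loci and among the leading Cd81-high transcripts.

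The last comparison joined both assays across 13598 genes, asking whether genes with many specific peaks of a sorted population were more expressed in its assumed transcript counterpart. MRISC was paired with Cd81-high, CD34 SP with Cd81-low, CD138 with Sdc1-high and Myofibroblast with myofibroblast-like cells. The pairing was not tested, and the antibodies that define MRISC are not given in the sources used here. By the number of peaks, such genes were more expressed for MRISC in Cd81-high cells and were not for CD138 in Sdc1-high cells. The other 2 pairs depended on how the genes were chosen. The 200 genes with the most MRISC specific peaks had a median log2 ratio of 0.11 in Cd81-high cells, against −0.17 in random lists matched on expression and length (percentile 100). The same MRISC genes stood at percentile 0.0 in Sdc1-high and in myofibroblast-like cells. The 200 CD34 SP genes had percentile 91.5 in Cd81-low (median 0.01) and 0.08 in Cd81-high cells (30.4 with 50 kb windows). The 200 CD138 genes had percentile 0.0 in Sdc1-high cells (median −0.22), and the 200 Myofibroblast genes 7.17 in myofibroblast-like cells (median −0.10). Genes with 3 or more specific peaks of 1 population and none of the others were few. Those of MRISC (10 genes) stood at percentile 85.9 in Cd81-high and 99.8 in Sdc1-high, those of CD34 SP (20) at 25.8 in Cd81-low, those of CD138 (27) at 97.1 in Sdc1-high (46.4 with windows of 50 kb, 12 genes) and those of Myofibroblast (18) at 39.7 in myofibroblast-like cells. Ranked instead by the excess over the other populations, a ranking chosen after the data were seen, the 200 genes stood at percentile 100 for MRISC, 95.1 for CD34 SP, 0.01 for CD138 and 78.5 for Myofibroblast in those groups. The CD34 SP value fell to 46.5 with windows of 50 kb and to 22.9 with 500 genes, and in Sdc1-high cells the same 200 CD34 SP genes stood at 100. Of the 4 pairs, only MRISC in Cd81-high (high) and CD138 in Sdc1-high cells (low) kept their place under both rankings, both windows and both numbers of genes. The low place of CD138 genes was not particular to Sdc1-high cells. By excess they also stood at 0.06 in Cd81-high, 0.35 in Cd81-low and 1.85 in myofibroblast-like cells. They stood at 45.8 in mesothelium-like, 11.9 in crypt-top-like and 44.1 in the remaining stromal cells. Whether 5 length bins matched the longest genes was not tested. Genes are not independent replicates, and the assays used different mice, male for the peaks and female on DSS for the cells.

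**Figure D4:**
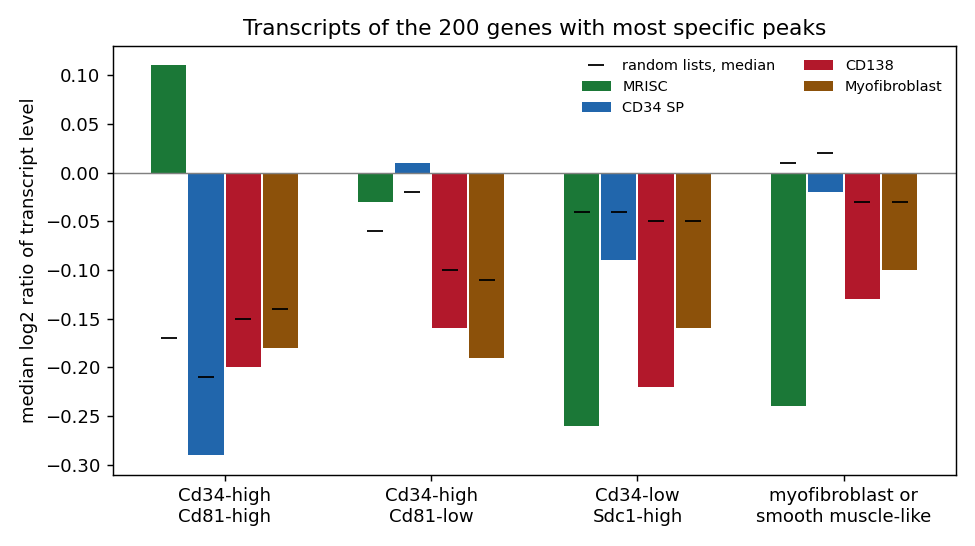
Median log2 ratio (y axis) of the 200 genes with the most specific peaks of each sorted population in 4 groups of the single-cell library, each group against the other stromal cells, with dashes at the median of 10000 matched random lists. MRISC genes in Cd81-high cells stood at 0.11 against −0.17 in random lists.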

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

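No test was run on the values given here, which were looked at only after the lists had been read. Of the peaks in the 4 total lists, 366 lay on sequences outside chromosomes 1 to 19, X and Y, which no comparison used. They drew attention as signal in a part of the data that was left out, with no control samples to set it against. MRISC had 79 of them, CD34 SP 53, CD138 150 and Myofibroblast 84. The specific lists held 10, 5, 75 and 18 such peaks in that order. Neither a technical nor a biological explanation was tested for them.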

How the results depend on the processing

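The alternatives with equal numbers of specific peaks, the peaks above the median score for words, the share of peaks at gene lists, the equal number for specific shares, the ranking of loci by excess, the Scrublet score limit and the gate without mesothelium-like cells were chosen after the data were seen. Over all results, 784 alternative values were computed. Of these 618 kept their direction and their side of the threshold or stayed within counting error, 67 moved and 29 reversed. Another 43 became weaker: 30 word odds ratios lost significance, and 6 gene list and 7 locus percentiles left the outer range of random lists. The 27 that became stronger were all percentiles that entered this range, 12 of gene lists and 15 of loci, and carry no test. No paired analysis was possible because each population has 1 peak list, the single-cell data are 1 library, and the data used here hold no values per replicate. This also rules out leaving out a replicate. Keeping doublets was planned as an alternative and changes nothing, since Scrublet marked none. Where a result moved, the cause was not tested unless the alternative itself shows it.

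With all lists limited to the peaks above their median score and specificity called again, the specific share was 26.5% in MRISC, 11.92% in CD34 SP, 42.27% in CD138 and 50.72% in Myofibroblast, and with equal numbers it was 39.58%, 37.29%, 46.1% and 59.34%. Mean overlaps with 50% of both peaks required were 35.7% for MRISC and CD34 SP, 19.4% for MRISC and CD138, 12.7% for MRISC and Myofibroblast, 21.4% for CD34 SP and CD138, 12.5% for CD34 SP and Myofibroblast, and 15% for CD138 and Myofibroblast. With equal numbers they were 54.0%, 41.6%, 31.3%, 45.2%, 32.7% and 30%. MRISC and CD34 SP stayed the closest pair in both.

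Tests at fixed gene lists past correction rose from 0 to 7 with windows of 50 kb, 5 with the nearest start and 4 by share. With 50 kb, immediate early genes (126 specific peaks of CD34 SP against 44.8) and inflammation-associated genes (141 against 67.0) had the lowest adjusted p, 0.0104 each. Neighbouring chemokine genes in the inflammation list, and neighbouring genes in the canonical Wnt list, can share peaks in these windows, which the random lists were not matched on. Matrix genes passed by number in CD34 SP and MRISC under both other assignments. The R-spondins and the MAP3K2-ERK5-KLF2 route passed in none. By share, matrix genes passed under both other assignments in CD34 SP only. In MRISC they did not pass with 50 kb (30.7% against 24.3%, adjusted permutation p = 0.052). By the nearest start they did not either (26.8% against 22.4%, adjusted permutation p = 0.761).

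For the 61 word calls, 366 odds ratios under other settings were computed, of which 329 kept direction and side, 30 lost significance and 7 reversed. The MEF2 word in CD138 reversed in the whole peak (0.926) and within GC bins (0.956), the GATA (0.933) and SOX (0.94) words in CD138 in the whole peak, the E-box word in MRISC within GC bins (0.952) and with equal numbers (0.907), and the NRF2 word in MRISC within GC bins (0.998).

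Shares of the single-cell groups depended on filters and clustering. Cd81-low cells made up 44.88% with at least 200 genes and at most 20% mitochondrial UMIs, 38.86% with at least 1000 genes and at most 5%, 41.01% and 36.43% at resolution 0.3 and 1.0, 40.52% with 4000 variable genes, 47.42% with 20 principal components and 42.28% without Scrublet scores above 0.3. Sdc1-high cells made up 11.68%, 16.98%, 32.23% and 18.86% under the first 4 of these, 7.46% with 20 principal components and 11.22% without high scores. Cd81-high cells moved to 11.25% with the stricter filter. Myofibroblast-like cells moved to 8.68% without high scores, since 17.5% of them had one. Mesothelium-like cells moved to 0.61% at resolution 1.0 and to 0.61% without high scores, and crypt-top-like cells to 5.71% with 4000 variable genes.

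The Rspo1 ratio of Cd81-high to Cd81-low was 8.95 with the looser filter, 18 at resolution 0.3, 18.72 with 4000 variable genes, 5.67 with 20 principal components and 19 without high scores. It could not be computed with the empty droplet profile subtracted, which left 0.0 CPM in Cd81-low cells. Sdc1-high over Cd81-high in Rspo1 was 0.99 and moved to 1.18 with the looser filter, 0.76 at resolution 0.3, 1.57 with 20 principal components and 1.23 without high scores. Rspo3 rose to 12.05 when the empty droplet profile was subtracted. Grem1 was 2.31 as a mean over cells, 2.65 with empty droplets subtracted, 2.96 with the looser filter, 2.28 at resolution 0.3 and 2.22 with 20 principal components. Klf2 was 3.01 as a mean over cells, 3.77 with empty droplets subtracted, 3.34 with the stricter filter, 3.17 at resolution 1.0 and 3.4 without high scores. In the gate, Rspo1 was 3.43 without mesothelium-like cells, Klf2 2.03 without thinning and 1.89 at 1500 UMIs, Grem1 2.34 and 1.65, and Rspo3 2.83 at 1500 UMIs.

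Of 182 list percentiles, 157 kept side and call, 6 left the outer 2.5% on either side, 12 entered it and 7 crossed the random median. Among genes with at least 100 UMIs, R-spondins stood at 89.65 in Sdc1-high and 98.03 in mesothelium-like cells, canonical Wnt ligands at 99.92 in Cd81-low and 99.54 in the remaining stromal cells, and Wnt antagonists at 12.25 and 99.17 in the same 2 groups. EGF family ligands stood at 99.71, reactive oxygen genes at 47.34 and sort markers at 0.03 in crypt-top-like cells. Sort markers stood at 84.78 in Cd81-high, 99.84 in Cd81-low and 27.01 in mesothelium-like cells, and matrix genes at 96.28 in Cd81-high cells. With a pseudocount of 10 CPM, R-spondins stood at 95.38 in Sdc1-high cells, BMP ligands at 1.86 in the remaining stromal cells, and canonical Wnt ligands at 99.83 in Cd81-low and 99.06 in the remaining cells. Noncanonical Wnt ligands stood at 1.04 in Cd81-high, 98.66 in Cd81-low and 2.01 in mesothelium-like cells, and Wnt antagonists at 3.14 in Sdc1-high and 7.58 in the remaining cells. Reactive oxygen genes stood at 47.14 in crypt-top-like, immediate early genes at 97.97 in myofibroblast-like and sort markers at 68.58 in Cd81-high cells. Rare classes are limited by depth, as the 79 crypt-top-like and 88 mesothelium-like cells show in their wide intervals.

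Of 84 percentiles of loci, 47 kept side and call, 7 left the outer 2.5%, 15 entered it and 15 crossed the random median. For the 200 MRISC loci in Cd81-low cells the percentile fell from 87.57 to 33.34 with 50 kb, 18.48 with 500 genes and 7.03 by excess with 50 kb. CD34 SP loci in Cd81-high cells rose from 0.08 to 30.41 with 50 kb, 23.63 by excess with 50 kb and 28.49 with 500 by excess. In Cd81-low cells they went from 91.5 to 46.54 and 22.89 under the last 2 settings. In Sdc1-high cells they went from 2.27 to 35.59 with 50 kb, 39.29 with 500 genes, 100 by excess, 99.97 by excess with 50 kb and 100 with 500 by excess. In myofibroblast-like cells they fell to 0.08 with 500 genes. Under the 5 settings in this order, CD138 loci went from 6.2 to 0.52, 0.04, 0.06, 0.61 and 0 in Cd81-high cells, and from 2.73 to 1.46, 0.06, 0.35, 1.68 and 0 in Cd81-low cells. Myofibroblast loci in Cd81-high cells fell from 13.08 to 0.14 with 500 genes, 0.01 by excess, 0.72 by excess with 50 kb and 0 with 500 by excess. In Sdc1-high cells they rose to 11.38 by excess and 20.82 by excess with 50 kb, and in myofibroblast-like cells to 78.49 by excess, 98.33 by excess with 50 kb and 64.46 with 500 by excess. Genes with specific peaks of CD138 only stood, with 50 kb, at 72.36 in Cd81-high, 77.99 in Cd81-low, 46.42 in Sdc1-high and 70.18 in myofibroblast-like cells. For the other 3 populations too few such genes were left with 50 kb for a value.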

Other observations

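The tests of explanations in this part were all chosen after the results they address were seen.

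Rspo1 was far higher in the 88 mesothelium-like cells than in fibroblasts. Free RNA is set aside as the source, since these cells had 526.0 CPM against 24.7 in empty droplets. Doublets with cells of another cluster are also set aside, because the lower bound of 477.1 CPM lay above the next highest cluster at 86.2 (upper bound 93.9). Whether mesothelial cells of a healthy colon have as much Rspo1 stays open, since the library is from 1 mouse on DSS and the design gives no other condition, so no biological explanation was tested. The Cd81 of these cells (1427.9 CPM) may bring some of them into a gate on CD81.

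The AP-1 word was frequent in the specific peaks of CD34 SP. Weaker peaks in the longer lists of the other populations did not account for it, as the odds ratio was 2.09 (1.98 to 2.21) with the same number of best-scored specific peaks from each population. GC content did not account for it either, with 2.05 (1.98 to 2.12) within GC bins. Immediate early transcripts, which include AP-1 subunits, were highest in Cd81-high cells and low in Cd81-low cells of the single-cell library. These levels cannot decide whether the word and the transcripts are linked, because the match of Cd81-low cells to CD34 SP was assumed. The assays also used different mice, male for the peaks and female on DSS for the cells. A state of the sorted CD34 SP cells, or their handling before the assay, may explain the word. Neither was tested.

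ETS and RUNX words were frequent in the specific peaks of CD138. GC content did not account for them, with odds ratios of 1.39 and 1.30 within GC bins and 1.24 as the lower bound of the smaller. A candidate explanation is blood cells in the sorted population, since both families are active in them and plasma cells carry CD138. The fixed markers of T, B or plasma, macrophage or dendritic and neutrophil cells (18 of 21 genes found) had 51 specific peaks of CD138, above the 16 to 40 of random lists (permutation p = 0.001). Cd2, Jchain and C1qa had 6 each. The sort excluded CD45, and Myofibroblast, in which both words were less frequent, also had 43 against 16 to 42 (permutation p = 0.0388), and MRISC, in which they were less frequent too, had 41 against 14 to 41 (permutation p = 0.0596), so the markers alone do not set CD138 apart. Of the 21 markers, 2 (Igkc and Jchain) reached 20 CPM in a stromal group of the single-cell library, and none is in another list. Igkc had 127.5 CPM in Sdc1-high cells against 7485.6 in cells that are not stromal. A regulatory state of CD138 cells themselves stays open and was not tested.

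The remaining marker lists gave these numbers of specific peaks in MRISC, CD34 SP, CD138 and Myofibroblast, none past correction. Adventitial fibroblast markers had 32, 24, 27 and 24, and crypt-top fibroblast markers 33, 37, 98 and 70. Markers of CD34-low lamina propria fibroblasts had 188, 165, 251 and 216, of which the window of Fgfr2 alone held 162, 143, 211 and 188. Pericyte markers had 25, 19, 29 and 27, those of interstitial cells of Cajal 20, 2, 39 and 30, glial markers 11, 10, 14 and 15, and mesothelial markers 17, 2, 10 and 8. Lymphatic endothelium had 14, 6, 17 and 19, blood endothelium 44, 12, 52 and 42, and epithelium 11, 6, 19 and 20. T cells had 6, 1, 8 and 4, B or plasma cells 5, 5, 16 and 19, macrophages or dendritic cells 25, 3, 21 and 16, neutrophils 5, 2, 6 and 4, red blood cells 3, 1, 1 and 1, and dividing cells 11, 3, 9 and 19. Macrophage or dendritic markers had an unadjusted p of 0.004 in MRISC, against 9.6 peaks in random lists.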
